A study of Handeliodendron bodinieri with 30 samples.

How the data were processed

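Poly-A messenger RNA of male and female flowers of Handeliodendron bodinieri was measured in 10 groups of 3 libraries: buds at anther stages 3-5, 6-7 and 8-9 and anthers at stages 6-7 and 8-9, in each sex. RNA was extracted with TRIzol and sequenced on a BGISEQ-500 as read pairs of 100 bases. Per the submitters' processing notes, reads were aligned with Bowtie2 and counted with RSEM, for which no version is given in the sources used here. The features are assembled contigs, named as members of a cluster or as single ones, and no genome build is named. The assembler and its settings are not given in the sources used here.

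Each library has 1 deposited table. Per the file headers, these deposited tables hold RSEM expected counts, FPKM (fragments scaled to contig length and library size) and the length of each contig in bases, other than which they give names from sequence searches. Contigs are listed in a table from an FPKM of 0.01 upward, and contigs not listed in a library were set to 0 there. In all, 128611 contigs were listed, 60894 of them in every library. Of all contigs 75.3% had a name from SwissProt or the nr collection at an E value of 1e-10 or below, and 60.1% belonged to 12821 clusters of more than 1 contig. Contigs were 200 to 36545 bases long, with a median of 1435. Libraries held 37657342 to 41096845 counted fragments, so that 3 counts, the floor per library used for bounds, stood at 0.071 to 0.0907 CPM (counts scaled to library size) in the groups. Such floors cover counting error only, not the spread between plants. Pairs of libraries within a group were checked for duplication: the chi-square per degree of freedom between them ran from 5.94 to 190.97, where 2 runs of 1 library would give about 1.

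Expected counts were rounded to whole numbers and scaled by TMM. Contigs passing filterByExpr (97727) were tested with edgeR 4.0.16 by its robust quasi-likelihood F test, with 1 mean per group over all 30 libraries and no replicate block. P-values were adjusted by Benjamini-Hochberg over all contigs tested, and a contig was called changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The 12 comparisons were female against male within each of the 5 combinations of tissue and stage, later against earlier stage in the anthers and in the buds of each sex (8-9 against 6-7 and 8-9 against 3-5), the sex by stage interaction in anthers and in buds, and anthers against buds at stages 6-7 and 8-9. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. A fold against a group at 0 reads is the mean CPM of the other group over the floor of 3 counts per library, rounded down.

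The lists were name patterns searched in the SwissProt and nr names: floral organ identity, early anther, tapetum regulators, pollen wall, callose and tetrad, meiosis, late pollen, anther-specific secreted proteins, cell death proteases, reactive oxygen, jasmonate, gibberellin, auxin, cytokinin, ethylene and abscisic acid, carpel and ovule, sugar, cell cycle, photosynthesis, flavonoid, lignin and secondary wall, lipid and cutin, pectin, heat shock, cytosolic ribosome, vascular and phloem, defence, and organelle genes. Some patterns were adapted to the wording of the names, from the names alone and before any test. Members that rose or fell were counted with adjustment over all contigs and over the list alone. Each list was also tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 28 lists of a comparison. Medians are also given with contigs unread in a group set at their bound.

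Genes were picked by 3 rules, and not all of those picked are named below. A panel of 43 anther, floral and meiosis genes was searched by name, and the matching contig with the highest mean CPM was used in every sex comparison; 36 were matched. For each comparison of groups, the 5 highest and 5 lowest log2 differences were taken among called contigs with an informative name, no overlap between the 3 libraries of the groups and a mean of at least 5 CPM in the higher group, 1 contig per name. For each list and sex comparison, up to 2 risen and 2 fallen called contigs of at least 5 CPM were taken. Panel contigs carry the name of the panel gene whose pattern their SwissProt or nr name matched, which can differ from the symbol of the best match: the contig of LAP6/PKSA is octaketide synthase 3 in SwissProt, that of CEP1 vignain, that of SEP3/AGL9 carries the symbol FBP2, and that of TDF1 is MYB35 in nr but MYB39 in SwissProt. Other symbols are those of the best SwissProt match. A contig that carries a name need not be the counterpart of that gene in this tree. The comparisons, tests, thresholds, lists, name rules and most alternatives were set before the data were examined.

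Alternatives were DESeq2 size factors in the same fit, DESeq2's Wald test, no filter beyond 1 read in total, a filter of 1 CPM in 3 libraries, no fold threshold, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with an FPKM of at least 1 in 3 libraries, each library left out in turn and, for 2 groups, a fit of their 6 libraries alone. For lists they were an estimated correlation, adjustment over the list alone and members of at least 1 CPM alone, and for the panel the sum over all matching contigs. Added after the data were examined were counts summed per cluster of contigs, fits without ribosomal RNA contigs, without both anther 6-7 libraries numbered 2 and without the 3 libraries with high ribosomal RNA or low scaling factors, a blocked fit of 6 libraries, and the test of the sex difference in anthers less that in buds at stage 8-9.

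The steps were tested on simulated data built from all 30 libraries, in which female and male anthers 8-9 were compared. Of 20000 simulated contigs 19530 were tested. Of 100 contigs changed 2-fold, 19 were recovered at the adjusted p and 17 at both thresholds, and of 100 changed 4-fold 63, with 3 false calls. In the simulation camera gave 5.12e-34 for a raised list and 0.724 for an unchanged one. Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means. For the same number in both sexes it ran from -0.065 to 0.067 in the bud and anther 8-9 comparisons, and was 0.368, 0.594 and 0.404 in anthers 6-7, where different numbers gave -0.501 to 0.42, so the numbers were not used as pairs. Other splits of the libraries were counted, all 10 for 2 groups and 30 drawn ones beside the real one for the rest. Contigs without a name entered the tests but no list, and reads, the assembly and contig sequences were not analysed here.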

Results

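Messenger RNA was measured in buds and anthers of male and female flowers of Handeliodendron bodinieri, a tree whose female flowers carry stamens that abort. Buds were taken in 3 diameter classes (under 1.3 cm, 1.3 to 1.6 cm and above 1.6 cm), which the labels give as anther stages 3-5, 6-7 and 8-9, and anthers were taken at stages 6-7 and 8-9. This gave 10 groups of 3 libraries, with 37657342 to 41096845 counted fragments per library over 128611 assembled contigs, of which 97727 were tested. Nothing in the sources says that the 3 libraries of a group came from separate plants, so the p-values measure the spread between these samples. Levels below are mean ± SD in CPM (counts scaled to library size, n = 3 libraries per group). Log2 differences are female minus male, later minus earlier or anther minus bud. Contigs of a list that are counted neither as risen nor as fallen did not pass.

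The first 2 principal components held 25.6% and 11.4% of the variance, and male and female anthers of stage 8-9 lay close together. The libraries numbered 2 of the male and the female anthers 6-7 stood apart from their groups: their mean correlation with the other libraries of the group was 0.817 and 0.846, against 0.951 and 0.949 between libraries 1 and 3. Ribosomal RNA contigs took 7.16% and 2.72% of the counts in these libraries and 29.4% in male buds 8-9, replicate 2, so that the male groups of the anther 6-7 and bud 8-9 comparisons carried more of it than the female ones.

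**Figure D1:**
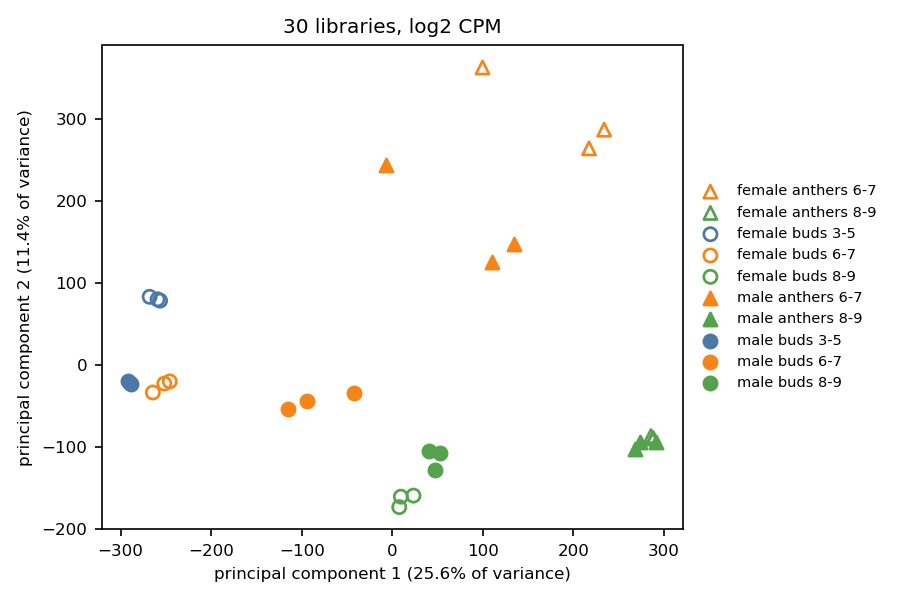
Positions of the 30 libraries on the first 2 principal components of log2 CPM, coloured by sex, tissue and stage.

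Female and male buds of the smallest class were compared to see whether the sexes differed before the tapetum genes rise. Genes that set floral organ identity were already higher in female buds. AG (CL12699.Contig3), which specifies stamens and carpels, stood at 17.4 ± 0.56 against 3.45 ± 0.079 CPM (log2 difference 2.33, adjusted p = 3.88e-10). AP3 (Unigene1187), which specifies petals and stamens, stood at 26.9 ± 0.61 against 4.37 ± 0.27 (2.62, adjusted p = 1.46e-10). PI (CL11247.Contig1), the partner of AP3, rose by 1.24, SEP3/AGL9 (Unigene4320) by 1.22 and PMADS1 (CL9318.Contig1), a close relative of the AP3 contig whose reads are uncertain to tell apart, by 2.65. The carpel gene CRC (CL4746.Contig3) was 7.13 ± 0.44 against 0.513 ± 0.14 (3.79). No transcript of the tapetum regulators DYT1 (Unigene25844, 0.0164 ± 0.028 CPM in male buds), AMS (CL1967.Contig8, 0 reads in male buds) or MS1 (CL9860.Contig2, 0.00847 ± 0.015 in male buds) stood above the floor of 3 counts per library in male buds.

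In these buds 4128 contigs were higher and 3479 lower in females, 7607 in all. In the floral organ identity list 27 of 70 contigs rose and 1 fell (30 and 2 adjusted per list). Its median was 0.93, or 0.89 with contigs unread in a group set at their bound, and its adjusted p 6.94e-09 (0.456 with an estimated correlation between members, written below as with correlation). Of 44 carpel and ovule contigs 9 rose and 0 fell (median 0.62, adjusted p = 0.00247; 0.456 with correlation). Among photosynthesis contigs 4 rose and 4 fell (median 0.39, adjusted p = 0.00994; 0.834 with correlation). Of 666 cytosolic ribosomal protein contigs 15 rose and 23 fell (median -0.28, adjusted p = 3.16e-05; 0.456 with correlation). The other 24 lists had adjusted p from 0.0524 to 0.941, and over the 28 lists 271 members rose and 164 fell (284 and 164 adjusted per list).

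Single contigs moved further in these smallest buds. A chalcone synthase contig (CL1944.Contig5), the entry enzyme of flavonoid synthesis, was 265 ± 25 against 0.368 ± 0.55 CPM (9.47), although its 12-contig cluster changed less (3.79). A photosystem I subunit contig, PSAF (Unigene12494), was 8.29 ± 0.60 CPM in females and had 0 reads in males, at least 110-fold higher. Higher in females were also a pectinesterase inhibitor, PMEI (Unigene31451, 3.70), a thaumatin-like protein (Unigene17908, 3.04), a vignain protease (Unigene21579, 2.45), and the lipase At5g45670 (Unigene800, 1.53). So was 1 contig of the superoxide dismutase SODCC.1 (Unigene17903, 3.15), whose other contig Unigene16836 went the other way (-1.36), and so the change of the gene is uncertain. Lower were the gibberellin oxidase 20ox2 (CL3077.Contig3, -2.48), the heat stress factor HSFA6b (CL7308.Contig3, -1.38), the Rubisco small subunit RBCS (Unigene28217, -1.66) and the sugar carrier MSSP2 (Unigene17075, -6.44). Counted per cluster of contigs, 2403 units differed in place of 7607, and on log2(FPKM + 1) 4152 contigs did.

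Buds of stage 6-7 were compared to see whether the sexes differed in tapetum regulators at that stage. Several of these were lower in female buds. DYT1 (Unigene25844), an early tapetum factor, was 0.0268 ± 0.027 against 5.04 ± 3.7 CPM (-7.39, adjusted p = 0.000682). AMS (CL1967.Contig8), which acts after it, was 0.0358 ± 0.062 against 10.9 ± 5.4 (-8.13, adjusted p = 2.44e-08) and bHLH91 (CL3276.Contig5), a partner of that family, 0.179 ± 0.067 against 18.0 ± 5.9 (-6.62). Jasmonate genes were also lower in female buds: DAD1 (Unigene14959), a lipase of the first step, at 0.698 ± 0.33 against 4.46 ± 1.6 (-2.67), and OPR3 (CL8295.Contig5), a late enzyme, at 43.1 ± 3.2 against 206 ± 15 (-2.25). Among the secreted proteins the stamen-specific FIL1 contigs were lower, CL5303.Contig2 at 0.331 ± 0.27 against 145 ± 61 (-8.76) and CL5303.Contig1 at 0.00893 ± 0.015 against 15.7 ± 7.6. The 2 contigs share a cluster, and how their reads divide is uncertain.

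Of the tested contigs 5954 were higher and 9645 lower in female buds 6-7, 15599 in all. Among tapetum regulators 3 of 50 rose and 13 fell (5 and 16 adjusted per list; median -0.26, or -0.14 at the bound, adjusted p = 0.0304; 0.733 with correlation). Of 229 jasmonate contigs 12 rose and 70 fell (median -0.43, -0.37 at the bound, adjusted p = 0.000185; 0.405 with correlation). Of 586 ethylene and abscisic acid contigs 33 rose and 125 fell (median -0.45, -0.38 at the bound, adjusted p = 0.00299; 0.363 with correlation). Of 88 cell death protease contigs 4 rose and 28 fell (median -0.61, -0.58 at the bound, adjusted p = 0.00299; 0.164 with correlation). Of 9 anther-specific secreted contigs 0 rose and 3 fell (median -0.51, adjusted p = 0.0372; 0.363 with correlation). Cell cycle contigs went up, with 23 of 268 risen and 14 fallen (median 0.40, adjusted p = 0.00116; 0.164 with correlation), as did photosynthesis, with 12 risen and 4 fallen (median 0.39, adjusted p = 0.0222; 0.768 with correlation). The other 21 lists had adjusted p from 0.119 to 0.842, and over all lists 372 members rose and 771 fell (399 and 800 adjusted per list).

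Among single genes of buds 6-7, the oxidases RBOHE (Unigene27650, -3.86) and RBOHD (Unigene10167, -7.47) were lower in females, and a second RBOHD contig (Unigene10164) had 0 reads against 50.9 ± 47, at least 630-fold lower. The jasmonate repressor TIFY10B (CL12705.Contig2) had 0 reads against 166 ± 76 (at least 2000-fold lower, -3.15 for its cluster). The defence regulator WRKY40 (CL2050.Contig13) had 0 against 121 ± 83 (at least 1500-fold, -2.14 for its cluster) and the auxin repressor IAA26 (Unigene29317) 0 against 46.1 ± 6.5 (at least 570-fold). Lower were also the cell death protease CEP1 (CL126.Contig10, -2.26), a further vignain (CL4411.Contig5, -4.36), the gibberellin enzyme KAO1 (Unigene3705, -3.98), and the regulator CIGR1 (CL8798.Contig3, -3.61). The same held for a PR-4A protein (Unigene24684, -5.14), CYP75B2 (Unigene14288, -6.46), PGIP (Unigene9997, -3.32), the laccase TT10 (Unigene21629, -7.61) and the lipase At5g41890 (CL6277.Contig2, -9.53). Higher were the chalcone synthase CHS1 (Unigene26821, 1.94), the abscisic acid hydroxylase CYP707A4 (Unigene38099, 5.35), the cytokinin receptor AHK4 (Unigene42777, 2.02), and the response regulator ARR4 (Unigene20759, 2.36). With them rose the cyclin CYCD1-1 (CL3935.Contig2, 1.87), the auxin receptor AFB2 (Unigene3943, at least 130-fold, 0 reads in males) and the aquaporin PIP2-5 (Unigene6620, at least 1600-fold). The pollen wall enzyme CYP703A2 (CL2146.Contig3) was lower as a contig (-4.10) but not as a 20-contig cluster (0.06). Over 5 other settings of contigs, libraries and scaling the adjusted p of the tapetum list ran from 0.0269 to 0.406 and that of the secreted list from 0.0292 to 0.234. Per cluster 6400 units differed, and 8132 contigs on log2(FPKM + 1), where RBOHE was not called.

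Buds of stage 8-9 were compared because male buds then make the pollen wall. Female buds held little of several wall transcripts that were abundant in male buds. CYP703A2 (CL2146.Contig3), a hydroxylase of wall fatty acids, was 0.824 ± 0.66 against 521 ± 90 CPM (-9.30, adjusted p = 1.43e-10), and ACOS5 (Unigene33811), which activates those acids, was 4.50 ± 1.4 against 645 ± 66 (-7.16, adjusted p = 2.69e-11). The contig matched to LAP6/PKSA (Unigene26839), a polyketide synthase, was 0.667 ± 0.78 against 766 ± 52 (-10.15), MS2 (CL7301.Contig5), a fatty acyl reductase, 0.480 ± 0.79 against 712 ± 73 (-10.52), and the exporter ABCG26 (CL4960.Contig2) 0.377 ± 0.49 against 358 ± 69 (-9.87). Regulators were low too, with AMS (CL1967.Contig8) at 0.137 ± 0.096 against 30.3 ± 4.0 (-7.74), MS1 (CL9860.Contig2) at 0.0728 ± 0.072 against 60.8 ± 8.0 (-9.63) and bHLH91 (CL3276.Contig5) at 0.113 ± 0.11 against 124 ± 31 (-10.05). A contig named MYB35 (TDF1, a tapetum factor) in nr but MYB39 in SwissProt (CL5159.Contig2) was not among them, at 5.54 ± 0.20 against 3.13 ± 0.69 (0.82, adjusted p = 0.0995, and called at 1.09 on log2(FPKM + 0.1)). The callose-degrading glucanase A6 (CL7260.Contig2) was 1.02 ± 1.4 against 1170 ± 57 (-10.16), QRT3 (CL10372.Contig1), which frees microspores from the tetrad, 2.27 ± 0.18 against 135 ± 12 (-5.90), and CYP704B1 (CL11826.Contig11) 8.89 ± 1.9 against 628 ± 53 (-6.14).

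In all, 7335 contigs were higher and 9012 lower in female buds 8-9, 16347 together. Of 50 tapetum regulator contigs (15 units when summed per cluster) 0 rose and 28 fell (0 and 29 adjusted per list, median -2.84, or -2.80 at the bound, adjusted p = 5.99e-22). Of 33 pollen wall contigs 2 rose and 19 fell (2 and 20 adjusted per list; median -3.18, or -3.11 at the bound, adjusted p = 1.07e-11). Of 20 callose and tetrad contigs 0 rose and 7 fell (median -0.57, -0.52 at the bound, adjusted p = 0.00103). Cell cycle contigs were higher, with 48 of 268 risen and 10 fallen (median 0.54, adjusted p = 3.39e-06); these 4 lists also passed with estimated correlation. Of 229 jasmonate contigs 14 rose and 68 fell (median -0.18, adjusted p = 0.00103; 0.414 with correlation). Of 138 flavonoid contigs 5 rose and 20 fell (median -0.38, adjusted p = 0.0226; 0.414 with correlation). Of 666 ribosomal protein contigs 19 rose and 43 fell (median -0.22, -0.20 at the bound, adjusted p = 0.00476; 0.414 with correlation). Of 44 carpel and ovule contigs 8 rose and 2 fell (median 1.01, 0.89 at the bound, adjusted p = 0.00588; 0.397 with correlation). In the photosynthesis list 9 rose and 5 fell (median 0.46, adjusted p = 0.0398; 0.803 with correlation). The other 19 lists had adjusted p from 0.0552 to 0.951, and over all lists 528 members rose and 766 fell (558 and 788 adjusted per list).

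Further genes low in female buds 8-9 were FIL1 (CL5303.Contig2, 0.891 ± 1.1 against 1040 ± 260, -10.18), the receptor BAM2 (CL1774.Contig6, -10.29), the spermidine transferase SHT (Unigene32322, -10.07), and the chalcone synthase CHSA (Unigene20354, -9.31). So were SWEET9 (Unigene49260, -10.41) and SWEET7B (Unigene34808, -7.73), both sugar exporters, the polygalacturonase PGA3 (CL3936.Contig2, -10.33), TIFY10B (CL12705.Contig2, -12.52, and -3.40 for its cluster), the oxidase RBOHE (Unigene27650, -5.64), DAD1 (Unigene14959, -3.49) and OPR3 (CL8295.Contig5, -1.53). The patatin-like PLP3 (Unigene6458) had 0 reads against 308 ± 150 (at least 4100-fold lower) and the factor GAM1 (Unigene21657) 0 against 8.75 ± 4.3 (at least 110-fold). Higher in female buds were the ovule growth gene ANT (CL11989.Contig1, 56.7 ± 2.4 against 17.2 ± 1.1, 1.72), FBP2 (Unigene37595, 2.97), GASA1 (Unigene4015, 6.65), and ARF2 (Unigene26914, 7.62). Higher too were RBOHC (Unigene30113, 4.85), the proline-rich APG (Unigene1052, 3.24), CYP76B6 (Unigene31644, 41.7 ± 4.1 against 0 reads, at least 470-fold) and EIL3 (Unigene47964, at least 120-fold). Of the called contigs 44.9% were higher in females, but 59.5% on log2(FPKM + 1) and 62.5% on log2(FPKM + 0.1). There the median of all contigs lay at 0.159 and 0.264 and the ribosomal list did not pass (adjusted p = 0.243 and 0.144, from 0.000338 to 0.243 over the 5 settings; 17 rose and 11 fell on the former). Per cluster 6785 units differed, and 10027 contigs on log2(FPKM + 1).

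**Figure D2:**
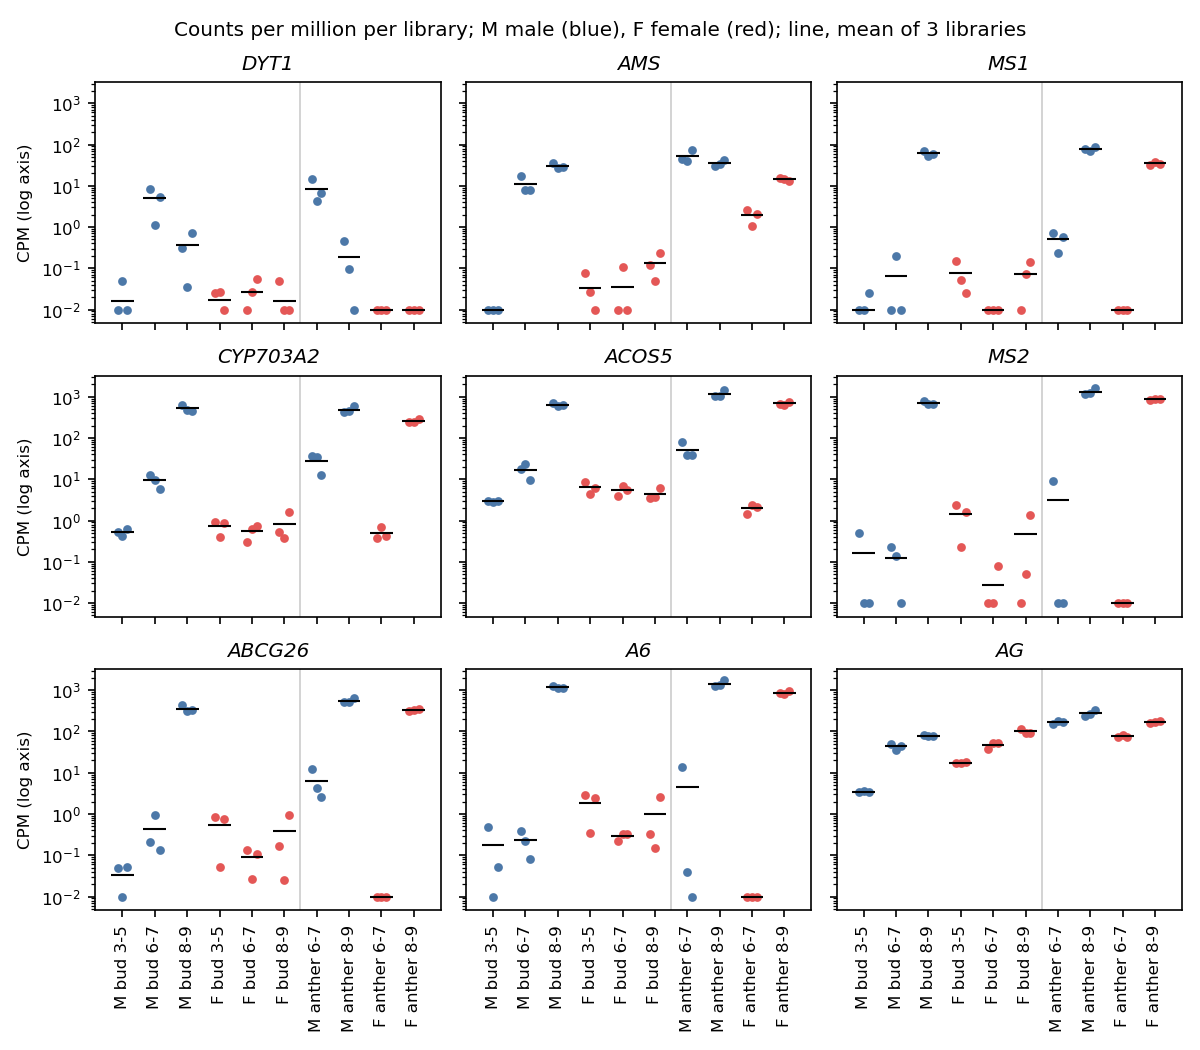
CPM of 8 tapetum and pollen wall genes and of AG in the 30 libraries, on a log scale with levels under 0.01 drawn at 0.01, and group means.

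Dissected anthers of stage 6-7 were compared to see whether the anther itself differed. Female anthers had 0 reads of DYT1 (Unigene25844) against 8.40 ± 5.2 CPM in male anthers (at least 92-fold lower, adjusted p = 9.73e-05). They had 0 reads of bHLH91 (CL3276.Contig5) against 75.3 ± 17 (at least 830-fold lower, adjusted p = 2.13e-11; -3.21 for its cluster), and less AMS (CL1967.Contig8), 1.91 ± 0.80 against 52.6 ± 18 (-4.76). Of the pollen wall genes, ACOS5 (Unigene33811) was 1.98 ± 0.51 against 51.8 ± 24 (-4.71), CYP703A2 (CL2146.Contig3) 0.491 ± 0.16 against 27.6 ± 13 (-5.85, and -1.24 for its cluster) and ABCG26 (CL4960.Contig2) 0 reads against 6.40 ± 5.1 (at least 70-fold lower). FIL1 (CL5303.Contig2) was 0.0641 ± 0.077 against 446 ± 150 (-12.66). The MYB35/MYB39 contig (CL5159.Contig2), whose match to TDF1 is uncertain, was higher and ran from 4.36 to 14.5 CPM in the 3 female and from 0.792 to 1.75 in the 3 male libraries (3.15, adjusted p = 1.06e-06). Higher in female anthers were also CEP1 (CL126.Contig10), a protease of tapetal death, at 406 ± 130 against 41.3 ± 29 (3.30), and a PR-1 protein (CL1838.Contig1) at 23.5 ± 6.9 against 0.422 ± 0.30 (5.73). The defence list leaned the other way without passing (18 of 120 rose, 37 fell, adjusted p = 0.472).

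In these anthers 9406 contigs were higher and 11805 lower in females, 21211 in all. Of 50 tapetum regulator contigs 1 rose and 20 fell (1 and 22 adjusted per list, median -1.77, or -1.33 at the bound, adjusted p = 5.36e-09, or 0.0728 with correlation). Of 33 pollen wall contigs 3 rose and 18 fell (3 and 19 adjusted per list; median -1.95, adjusted p = 0.000245; 0.0992 with correlation). Of 43 early anther contigs 3 rose and 14 fell (median -0.99, adjusted p = 0.0267; 0.634 with correlation). Growth lists were lower: of 268 cell cycle contigs 9 rose and 94 fell (median -0.90, -0.83 at the bound, adjusted p = 5.36e-09) and of 666 ribosomal protein contigs 10 rose and 191 fell (median -0.77, -0.74 at the bound, adjusted p = 3.7e-12), and both passed with estimated correlation. So were auxin (45 of 554 rose, 156 fell, median -0.48, -0.43 at the bound, adjusted p = 0.00612; 0.454 with correlation) and lipid and cutin (32 of 332 rose, 92 fell, median -0.54, adjusted p = 0.00141; 0.175 with correlation). Pectin (32 of 235 rose, 67 fell, median -0.55, adjusted p = 0.0468; 0.608 with correlation) and photosynthesis (4 rose, 25 fell, median -0.68, adjusted p = 0.00091; 0.784 with correlation) were lower too. Cell death proteases rose, 23 of 88 with 7 fallen (median 0.64, adjusted p = 6.54e-06; 0.0135 with correlation), as did vascular markers, 7 of 40 with 1 fallen (median 0.64, adjusted p = 0.0191; 0.0992 with correlation). The other 17 lists had adjusted p from 0.17 to 0.986, and over all lists 550 members rose and 1141 fell (561 and 1196 adjusted per list).

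Among other genes low in female anthers 6-7 were both contigs of the jasmonate methyltransferase JMT (CL7266.Contig1, -9.94, and Unigene17705, -7.68), the sugar exporter SWEET7 (Unigene17504, 0.189 ± 0.20 against 105 ± 67, -9.32), and the lignin enzyme CCR2 (Unigene1492, -5.48). Low too were the cyclin CYCD3-1 (CL5540.Contig1, -3.66), the chaperone HSC80 (Unigene33378, -3.06), IAA26 (Unigene29317, 0 reads against 8.86 ± 1.8, at least 97-fold lower), ARF19 (Unigene5269, at least 150-fold lower) and the carpel gene CRC (CL4746.Contig3, 1.60 ± 1.4 against 23.6 ± 12, -3.93). High in female anthers were GASA1 (Unigene4015, 244 ± 91 against 2.39 ± 2.7, 6.72), the transporter TDT (CL10337.Contig1, at least 1800-fold, and 3.34 for its cluster), RPS3A (Unigene33752, at least 330-fold) and the MADS-box gene CMB1 (Unigene8199, 3.60). With them stood HSP83A (CL10612.Contig3, 4.31), ARF2 (Unigene26914, 8.81), the laccase TT10 (CL11601.Contig2, 6.44) and At1g06620 (Unigene30995, 4.64). In the vignain cluster of CEP1 the contigs named CYSEP went both ways (CL126.Contig1 6.32, CL126.Contig8 at least 670-fold lower), the cluster rose by 1.89, and the member behind each read is uncertain. A fit of only the 6 libraries called 2740 contigs, 57.8% of them higher in females against 44.3% among the 21211, and did not call CRC (-3.88, adjusted p = 0.0527), CEP1 (3.34, adjusted p = 0.059) or the contig CL5159.Contig2 (3.21, adjusted p = 0.0513), at folds near those above. The same fit with a block for the replicate number called 12901, these genes among them. Both libraries numbered 2 deviated together (correlation 0.594). Deviations sum to 0 per group, so 0.353 to 0.42 for 1 and 3 largely follows. Per cluster 9748 units and on log2(FPKM + 1) 11147 contigs differed. Per cluster the early anther, pectin, tapetum and vascular lists did not pass, with the highest adjusted p of the 5 settings (0.00349 to 0.694, 0.0112 to 0.574, 5.21e-09 to 0.0535 and 0.00396 to 0.138).

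Anthers 8-9 were compared to see how far female ones had come. These held several tapetum and pollen wall transcripts scarce in female buds of that class. MS2 (CL7301.Contig5) stood at 876 ± 29 against 1320 ± 230 CPM in male anthers (-0.60, adjusted p = 0.825), A6 (CL7260.Contig2) at 871 ± 63 against 1450 ± 240 (-0.73, adjusted p = 0.759) and ACOS5 (Unigene33811) at 687 ± 44 against 1190 ± 220 (-0.79, adjusted p = 0.0988). LAP6/PKSA differed by -0.68 (adjusted p = 0.779). CYP703A2 stood at 263 ± 28 against 487 ± 82 (-0.89, adjusted p = 0.163) and CYP704B1 at 446 ± 18 against 832 ± 150 (-0.90, adjusted p = 0.297). ABCG26 was at 335 ± 16 against 563 ± 78 (-0.75, adjusted p = 0.537) and QRT3 at 141 ± 10 against 197 ± 31 (-0.48, adjusted p = 0.436). None passed, which does not show equal levels. Spread came from all 30 libraries, and for each gene every female library lay below every male one. The regulator bHLH91 (CL3276.Contig5) was lower, at 26.7 ± 0.40 against 87.2 ± 15 (-1.71, adjusted p = 0.00105). MS1 (CL9860.Contig2) at 34.9 ± 2.9 against 77.7 ± 7.7 did not pass (-1.15, adjusted p = 0.0884, and from 1e-06 to 0.223 over the other settings, 7 of which called it). The MYB35/MYB39 contig (CL5159.Contig2) was higher, at 4.64 ± 0.14 against 0.770 ± 0.31 (2.59, adjusted p = 2.93e-05). CEP1 (CL126.Contig10) was above the male level here too, at 362 ± 33 against 18.7 ± 7.7 (4.27, and 1.20 for its cluster).

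Here 6466 contigs were higher and 4601 lower in females, 11067 in all. Of 50 tapetum regulator contigs 1 rose and 17 fell (1 and 22 adjusted per list, median -1.31, or -1.30 at the bound, adjusted p = 4.73e-08, or 0.116 with correlation). Of 33 pollen wall contigs 0 rose and 1 fell, TKPR2 (CL3309.Contig1, -1.47), with a median of -0.75 and an adjusted p of 0.131. Cell death proteases were higher, 23 of 88 with 5 fallen (median 0.43, adjusted p = 7.34e-06), and so were vascular markers, 13 of 40 with 1 fallen (median 0.74, adjusted p = 8.99e-06); both passed with estimated correlation. Of 138 flavonoid contigs 22 rose and 8 fell (median 0.37, adjusted p = 0.0131; 0.471 with correlation). Of 44 carpel and ovule contigs 4 rose and 0 fell (median 0.33, adjusted p = 0.0186; 0.504 with correlation), among them SPT (CL11061.Contig2, 1.44) and BEL1 (CL3473.Contig1, 1.62). The other 23 lists had adjusted p from 0.0709 to 0.957, and over all lists 459 members rose and 432 fell (488 and 476 adjusted per list).

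Among the contigs higher in female anthers 8-9 were the chitinase Cht4 (CL50.Contig5, 551 ± 76 against 4.53 ± 3.1, 6.92), a PR-1 protein (CL1838.Contig2, 6.87), and the pectinesterase PECS-2.1 (CL11695.Contig1, 393 ± 19 against 1.79 ± 1.4, 7.77). The defence, pectin and lignin lists did not pass (adjusted p = 0.105, 0.813 and 0.0712). Higher were also the laccase LAC14 (CL11601.Contig1, 7.64) and a vacuolar-processing enzyme (CL6292.Contig3, at least 98-fold, 1.64 for its cluster). With them stood GASA1 (Unigene4015, 365 ± 22 against 0.117 ± 0.20, 11.56), the cytokinin oxidase CKX5 (CL3679.Contig1, 396 ± 3.7 against 0.148 ± 0.26, 3.09 for its cluster), and ARF2 (Unigene26914, at least 140-fold). TULP5 (Unigene48189, at least 670-fold), KAO1 (Unigene6546, 6.76), RAP2-7 (CL10206.Contig2, 4.11), CMB1 (Unigene8199, 2.49), RPS3A (Unigene33752, 4.35) and PP2A10 (Unigene21459, 1.58) were higher too. Lower were AAP3 (Unigene4817, 0 reads against 47.4 ± 28, at least 630-fold), LTP13 (Unigene2374, -3.67), the lipid transfer protein At5g64080 (Unigene24816, -5.34), HSF30 (CL3882.Contig2, -4.35), the protease CEP2 (Unigene586, -3.06), SWEET7 (Unigene17504, -2.13), AHK4 (Unigene16869, -3.07), LOX3.1 (CL6105.Contig1, -2.44) and BUBR1 (CL8137.Contig2, -2.04). AMS (CL1967.Contig8, -1.33, adjusted p = 0.031) lost its call when any 1 of the 6 libraries was left out (0.0586 to 0.112). Per cluster 5439 units and on log2(FPKM + 1) 6642 contigs differed, and per cluster the carpel and vascular lists did not pass, with the highest adjusted p of the 5 settings (0.0188 to 0.162 and 8.94e-06 to 0.0557).

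The same 97727 contigs were tested in buds and anthers of 1 stage from different libraries, and their calls were compared. At stage 6-7, 901 contigs were higher in females in both tissues against 573 for independent lists, 1390 were lower in both against 1165, and 3457 went opposite ways against 1648. At stage 8-9, 1583 were higher in both against 485, 1865 lower in both against 424, and 654 went opposite ways against 942. Without the fold threshold the stage 6-7 counts were 1278, 1854 and 5707 (against 1074, 1874 and 2838) and the stage 8-9 counts 2275, 2548 and 1301 (against 855, 795 and 1674).

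Male anthers of stage 8-9 were set against stage 6-7 to follow normal anther development. Pollen wall genes rose there. MS2 (CL7301.Contig5) went from 3.07 ± 5.3 to 1320 ± 230 CPM (8.72, adjusted p = 0.00068) and A6 (CL7260.Contig2) from 4.58 ± 7.9 to 1450 ± 240 (8.28, adjusted p = 0.00057). Their stage 6-7 reads lay almost wholly in replicate 1 (9.21, 0 and 0 CPM for MS2 and 13.7, 0.0388 and 0 for A6). Without it both stood under the floor of 3 counts per library, so that the size of their rise is uncertain, and both stayed called (adjusted p = 1.39e-05 and 1.39e-06). MS1 (CL9860.Contig2) rose from 0.516 ± 0.26 to 77.7 ± 7.7 (7.16), ABCG26 (CL4960.Contig2) from 6.40 ± 5.1 to 563 ± 78 (6.45) and CYP703A2 (CL2146.Contig3) from 27.6 ± 13 to 487 ± 82 (4.14). DYT1 (Unigene25844) fell from 8.40 ± 5.2 to 0.187 ± 0.25 (-5.46), and the meiotic cyclin SDS (CL3308.Contig1) from 6.56 ± 2.5 to 0.396 ± 0.22 (-4.04). The wax gene CER26 (Unigene11601, 470 ± 120 against 0 reads, at least 5700-fold), LBD20 (CL3906.Contig1, at least 1400-fold) and the wall protein GP1 (Unigene16754, 3140 ± 760 against 0.101 ± 0.056) were among the contigs with the largest rise. FCA (CL1080.Contig11, at least 1100-fold, -2.03 for its cluster) and the DELLA protein GAIPB (Unigene23597, at least 1500-fold) were among those with the largest fall.

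In male anthers 7714 contigs rose and 10344 fell with stage, 18058 in all. Of 33 pollen wall contigs 19 rose and 1 fell (21 and 2 adjusted per list; median 4.14, or 4.13 at the bound, adjusted p = 8.26e-11). Of 268 cell cycle contigs 12 rose and 98 fell (median -0.82, adjusted p = 2.56e-09), and both passed with estimated correlation. Of 46 meiosis contigs 1 rose and 16 fell (median -0.99, adjusted p = 0.000676; 0.543 with correlation). Among photosynthesis contigs 3 rose and 34 fell (median -0.87, adjusted p = 0.000384; 0.733 with correlation). The other 24 lists had adjusted p from 0.114 to 0.987, and over all lists 585 members rose and 848 fell (617 and 907 adjusted per list). Of the called contigs 42.7% rose, but 55.0% of the 6786 called from the 6 libraries alone, in which MS2 and A6 were not called (8.76 and 8.31, adjusted p = 0.0971 and 0.111), and 57.7% and 57.5% on log2(FPKM + 1) and log2(FPKM + 0.1). Per cluster 7816 units and on log2(FPKM + 1) 9340 contigs differed, and the photosynthesis list did not pass without the 3 doubted libraries (adjusted p = 0.0604, the highest of the 5 settings).

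Female anthers were followed over the same stages. Pollen wall genes rose, some of them from 0 reads. From 0 reads A6 (CL7260.Contig2) went to 871 ± 63 CPM (at least 9600-fold, adjusted p = 3.12e-05) and MS2 (CL7301.Contig5) to 876 ± 29 (at least 9600-fold, adjusted p = 5.53e-05), and LAP6/PKSA (Unigene26839) by at least 5200-fold. ABCG26 (CL4960.Contig2) rose to 335 ± 16 (at least 3600-fold), MS1 (CL9860.Contig2) to 34.9 ± 2.9 (at least 380-fold) and bHLH91 (CL3276.Contig5) to 26.7 ± 0.40 (at least 290-fold, 1.82 for its cluster). ACOS5 (Unigene33811) rose from 1.98 ± 0.51 to 687 ± 44 (8.45), CYP703A2 (CL2146.Contig3) from 0.491 ± 0.16 to 263 ± 28 (9.10) and AMS (CL1967.Contig8) from 1.91 ± 0.80 to 14.2 ± 1.2 (2.87). CALS5 (Unigene3860), which builds the callose wall, fell from 84.5 ± 8.4 to 14.2 ± 0.88 (-2.58), and SDS (CL3308.Contig1) from 4.42 ± 2.7 to 0.315 ± 0.065 (-3.80). A MIEL1 ubiquitin ligase (CL5202.Contig3, at least 1000-fold), EXO70B1 (CL11139.Contig2, at least 910-fold) and HMG1 (CL4716.Contig11, at least 790-fold) fell to 0 reads, and their clusters changed by -1.34, -1.93 and -1.31.

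With stage, 9110 contigs rose and 7910 fell in female anthers, 17020 in all. Of 33 pollen wall contigs 24 rose and 0 fell (25 and 0 adjusted per list; median 4.33, or 3.81 at the bound, adjusted p = 3.05e-17), the only list of this comparison that also passed with estimated correlation. Of 50 tapetum regulator contigs 21 rose and 5 fell (median 0.19, adjusted p = 0.000355, or 0.388 with correlation). Of 46 meiosis contigs 1 rose and 23 fell (median -2.05, adjusted p = 6.3e-09; 0.0885 with correlation). Of 332 lipid and cutin contigs 78 rose and 12 fell (median 0.41, 0.39 at the bound, adjusted p = 6.18e-06; 0.0885 with correlation). Of 666 ribosomal protein contigs 143 rose and 32 fell (median 0.43, adjusted p = 1.07e-08; 0.102 with correlation). Floral identity (13 of 70 rose, 2 fell, median 0.62, adjusted p = 0.00368; 0.674 with correlation) and pectin (36 of 235 rose, 13 fell, median 0.23, adjusted p = 0.0335; 0.548 with correlation) went up too. So did anther-specific secreted contigs (3 of 9 rose, 1 fell, median 0.25, adjusted p = 0.0335; 0.243 with correlation). The other 20 lists had adjusted p from 0.133 to 0.943, and over all lists 821 members rose and 535 fell (853 and 572 adjusted per list). Of the called contigs 53.5% rose, against 67.6% on log2(FPKM + 1) and 71.8% on log2(FPKM + 0.1), where the median of all contigs lay at 0.161 and 0.327. From the 6 libraries alone 8535 contigs were called, on log2(FPKM + 1) 8594 and per cluster 7370 units, where the secreted, floral identity, pectin and tapetum lists did not pass (adjusted p = 0.259, 0.173, 0.142 and 0.463, the highest of the 5 settings).

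Male buds of stage 8-9 were set against stage 3-5 to follow the whole flower. Floral identity genes rose with the stamen genes. AP3 (Unigene1187) went from 4.37 ± 0.27 to 166 ± 14 CPM (5.24, adjusted p = 2e-14) and AG (CL12699.Contig3) from 3.45 ± 0.079 to 79.5 ± 2.9 (4.52, adjusted p = 3.22e-14). PI (CL11247.Contig1) went from 9.93 ± 0.28 to 215 ± 2.3 (4.44) and OPR3 (CL8295.Contig5) from 56.3 ± 4.1 to 605 ± 81 (3.43). AMS (CL1967.Contig8) rose from 0 reads to 30.3 ± 4.0 (at least 400-fold), and bHLH91 (CL3276.Contig5) to 124 ± 31 (11.74). A6 (CL7260.Contig2) rose to 1170 ± 57 (12.63), ABCG26 (CL4960.Contig2) to 358 ± 69 (13.26) and CYP703A2 (CL2146.Contig3) to 521 ± 90 (9.98, and 2.92 for its cluster). The terpene synthase TPS12 (CL1646.Contig2, at least 4800-fold, 6.43 for its cluster), TIFY10B (CL12705.Contig2, at least 4700-fold, 3.66 for its cluster), TIFY11B (CL1359.Contig5, at least 3100-fold, 3.60 for its cluster) and PLP3 (Unigene6458, at least 4100-fold) rose from 0 reads. XYL1 (Unigene37897, at least 2700-fold) and PIP2-5 (Unigene6620, at least 500-fold) fell to 0 reads.

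This stage comparison called 16423 risen and 12363 fallen contigs, 28786 in all. Tapetum regulators (31 of 50 rose, 0 fell, 31 and 0 adjusted per list, median 2.40, adjusted p = 3.84e-18) and pollen wall (23 of 33 rose, 3 fell, 25 and 3 adjusted per list, median 6.79, 6.50 at the bound, adjusted p = 1.86e-11) rose. So did callose and tetrad (11 of 20 rose, 0 fell, median 1.47, 1.19 at the bound, adjusted p = 8.91e-05) and cell death proteases (37 of 88 rose, 2 fell, median 1.22, 1.08 at the bound, adjusted p = 6.83e-06). Cell cycle contigs fell (22 of 268 rose, 122 fell, adjusted p = 2.03e-11), and all 5 passed with estimated correlation. Floral identity rose (38 of 70, 6 fell, median 1.84, 1.29 at the bound, adjusted p = 2.03e-11; 0.174 with correlation). So did jasmonate (83 of 229, 22 fell, median 0.45, adjusted p = 0.000245; 0.257 with correlation) and lipid and cutin (105 of 332 and 42 fallen adjusted per list, median 0.52, 0.44 at the bound, adjusted p = 0.00428; 0.246 with correlation). The rise held for ethylene and abscisic acid (171 of 586, 75 fell, median 0.49, 0.46 at the bound, adjusted p = 0.017; 0.268 with correlation) and carpel and ovule (18 of 44, 7 fell, median 0.87, adjusted p = 0.0165; 0.271 with correlation). Vascular markers (13 of 40 rose, 1 fell, median 0.37, adjusted p = 0.0291; 0.173 with correlation) and anther-specific secreted contigs (4 of 9 rose, 1 fell, median 0.63, adjusted p = 0.0424; 0.246 with correlation) rose. Photosynthesis fell (3 rose, 32 fell, median -0.46, adjusted p = 0.00112; 0.596 with correlation). Ribosomal protein contigs tested as lower (62 of 666 rose, 75 fell, adjusted p = 0.000335; 0.257 with correlation), with a median of -0.40 and a mean of 0.29, and per cluster 47 rose and 34 fell. The other 14 lists had adjusted p from 0.0889 to 0.953, and over all lists 1317 members rose and 923 fell (1355 and 952 adjusted per list). Of the called contigs 57.1% rose, against 44.5% on log2(FPKM + 1) and 43.6% on log2(FPKM + 0.1), where the median of all contigs lay at -0.117 and -0.208. Per cluster 12888 units were called and on log2(FPKM + 1) 16401 contigs, and the highest adjusted p of the 5 settings was 0.113 for the vascular list, per cluster, and 0.192 for the secreted list, without the 3 doubted libraries.

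Female buds over the same stages gained floral identity transcripts, while the pollen wall list did not pass (5 of 33 rose, 1 fell, adjusted p = 0.643). PI (CL11247.Contig1) rose from 23.5 ± 1.5 to 296 ± 22 CPM (3.66, adjusted p = 3.92e-11) and AP3 (Unigene1187) from 26.9 ± 0.61 to 212 ± 13 (2.98, adjusted p = 1.27e-11). AG (CL12699.Contig3) rose from 17.4 ± 0.56 to 100 ± 11 (2.52) and CRC (CL4746.Contig3) from 7.13 ± 0.44 to 31.9 ± 2.7 (2.16). CEP1 (CL126.Contig10) rose from 8.93 ± 3.5 to 109 ± 5.7 (3.61, and 2.01 for its cluster) and the meiosis gene MMD1 (CL1432.Contig1) from 1.11 ± 0.16 to 6.50 ± 2.1 (2.55). A6 (CL7260.Contig2) stood at 1.85 ± 1.3 and 1.02 ± 1.4 (-0.86, adjusted p = 0.672) and MS2 (CL7301.Contig5) at 1.40 ± 1.1 and 0.480 ± 0.79 (-1.53, adjusted p = 0.464). CKX5 (CL3679.Contig1, at least 1800-fold, 3.63 for its cluster), the yippee-like At4g27740 (CL617.Contig1, at least 1900-fold, 3.33 for its cluster), CRK10 (CL574.Contig31, at least 900-fold, 1.70 for its cluster) and STP13 (CL8543.Contig5, at least 750-fold, 2.92 for its cluster) rose from 0 reads. UVH6 (Unigene5479, at least 640-fold), PDC2 (Unigene10179, at least 610-fold) and CIA2 (CL4869.Contig4, at least 610-fold, -1.29 for its cluster) fell to 0 reads.

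In female buds 12129 contigs rose and 9488 fell, 21617 in all. Cell death proteases rose (37 of 88, 3 fell, median 0.94, 0.92 at the bound, adjusted p = 7.14e-07; 0.00994 with correlation). So did floral identity (27 of 70, 8 fell, 33 and 8 adjusted per list, median 0.92, adjusted p = 7.14e-07; 0.408 with correlation). The same held for carpel and ovule (17 of 44, 5 fell, median 0.86, adjusted p = 0.00171; 0.35 with correlation) and vascular markers (9 of 40, 2 fell, median 0.45, adjusted p = 0.00822; 0.133 with correlation). Flavonoid (17 of 138 rose, 46 fell, median -0.94, adjusted p = 0.00171; 0.35 with correlation) and cell cycle contigs (18 of 268 rose, 56 fell, median -0.46, adjusted p = 0.00166; 0.133 with correlation) went down. Photosynthesis (4 rose, 32 fell, median -0.60, adjusted p = 0.000582; 0.841 with correlation) and ribosomal protein contigs (20 of 666 rose, 56 fell, median -0.34, adjusted p = 0.00018; 0.35 with correlation) went down as well. The other 20 lists had adjusted p from 0.118 to 0.918, and over all lists 853 members rose and 687 fell (882 and 707 adjusted per list). On log2(FPKM + 1) 11690 contigs were called and per cluster 9125 units, where the vascular list did not pass (adjusted p = 0.369, the highest of the 5 settings).

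**Figure D3:**
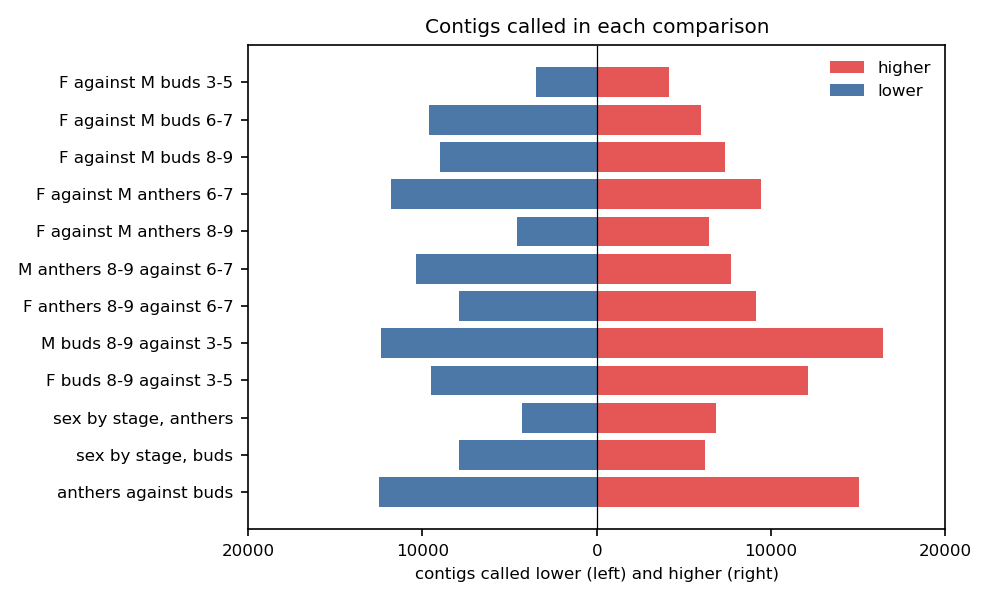
Contigs called higher and lower in each of the 12 comparisons.

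Whether the sexes changed differently between anther stages 6-7 and 8-9 was tested as an interaction. Some pollen wall genes that were lower in female anthers at stage 6-7 rose more there than in male anthers, ACOS5 (Unigene33811) by 3.93 and CYP703A2 (CL2146.Contig3) by 4.96 on the log2 scale, while MS2, A6, QRT3 and CYP704B1 did not pass (adjusted p = 0.0844, 0.0507, 0.069 and 0.29). For AMS (CL1967.Contig8, 3.43) and RBOHE (Unigene27650, 3.21) the means rose with stage in females and fell in males, while CALS5 (Unigene3860) fell further in females, by -1.53. In anthers 6848 contigs had a positive and 4272 a negative interaction, 11120 in all. Positive lists were cell cycle (56 of 268 rose, 9 fell, adjusted p = 1.62e-08) and ribosomal proteins (92 of 666 rose, 11 fell, adjusted p = 9.63e-13). Negative was heat shock (11 of 396 rose, 39 fell, adjusted p = 0.0228), and these 3 passed with estimated correlation. Pollen wall (11 of 33 rose, 1 fell, adjusted p = 0.0061; 0.456 with correlation) and tapetum (16 of 50 rose, 1 fell, adjusted p = 0.0144; 0.47 with correlation) were positive too. So were carpel and ovule (7 of 44 rose, 1 fell, adjusted p = 0.0061; 0.47 with correlation) and photosynthesis (14 rose, 0 fell, adjusted p = 0.00266; 0.599 with correlation). The same direction held for early anther (6 of 43 rose, 2 fell, adjusted p = 0.0228; 0.485 with correlation) and defence contigs (19 of 120 rose, 5 fell, adjusted p = 0.0144; 0.511 with correlation). Auxin, flavonoid and lipid and cutin were positive (81, 32 and 56 rose, 19, 8 and 16 fell) and meiosis negative (1 rose, 2 fell), each with an adjusted p of 0.0144; 0.47 with correlation. Over all lists 636 members rose and 277 fell (740 and 309 adjusted per list), 13 lists passed, and the 15 others had adjusted p from 0.064 to 0.914. Without female anther 6-7 replicate 2 the count was 18022, without both anther 6-7 libraries numbered 2 it was 18015, and without the 3 doubted libraries it was 18252. Per cluster 4889 units were called, and the tapetum list passed neither there nor on log2(FPKM + 1) nor without the 3 doubted libraries (adjusted p = 0.931, 0.761 and 0.311, the highest of the 5 settings). On log2(FPKM + 1) pollen wall (5 rose, 3 fell, adjusted p = 0.435) and lipid and cutin (0.0703) did not pass. Per cluster early anther did not (0.335), and meiosis passed on neither FPKM scale (0.11 on log2(FPKM + 1) and 0.0545 on log2(FPKM + 0.1)); these too were the highest of the 5 settings.

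In buds (8-9 against 3-5) the same interaction (female less male change) was negative for several pollen wall and tapetum genes that rose in males. ACOS5 (Unigene33811) differed by -8.29, CYP703A2 (CL2146.Contig3) by -9.80, ABCG26 (CL4960.Contig2) by -13.80 and bHLH91 (CL3276.Contig5) by -11.03. The callose gene CALS5 (Unigene3860) rose in female buds too, from 4.18 ± 0.46 to 9.84 ± 1.7 CPM (1.23, and 0.68 and not called on log2(FPKM + 1)), but less than in males (-1.15). The MYB35/MYB39 contig (CL5159.Contig2) rose in both sexes, from 0.307 ± 0.0064 to 5.54 ± 0.20 in females (4.16) and from 0.274 ± 0.046 to 3.13 ± 0.69 in males (3.50), and its interaction did not pass (0.66, adjusted p = 0.518). OPR3 (CL8295.Contig5, -2.01) and the identity genes AG (CL12699.Contig3, -2.00) and AP3 (Unigene1187, -2.27) rose less in females. AG and AP3 started there from a higher level at stage 3-5. The mean of DAD1 (Unigene14959, -4.95) rose in males, from 0.266 to 2.86 CPM, and was lower at stage 8-9 in females, 0.251 against 0.735. In buds 6236 contigs had a positive and 7929 a negative interaction, 14165 in all. Tapetum (0 of 50 rose, 21 fell, 0 and 22 adjusted per list, adjusted p = 7.67e-21) and pollen wall (1 of 33 rose, 16 fell, adjusted p = 5.77e-12) were negative. So was callose and tetrad (0 of 20 rose, 8 fell, adjusted p = 3.93e-05), cell cycle (51 of 268 rose, 5 fell, adjusted p = 5.52e-06) was positive, and these 4 passed with estimated correlation. Flavonoid (5 of 138 rose, 23 fell, adjusted p = 0.000972; 0.313 with correlation) and floral identity (3 of 70 rose, 19 fell, adjusted p = 0.000319; 0.504 with correlation) were negative. Jasmonate (19 of 229 rose, 69 fell, adjusted p = 0.000265; 0.353 with correlation) and lipid and cutin (18 of 332 rose, 51 fell, adjusted p = 0.00654; 0.338 with correlation) were as well. Over all lists 432 members rose and 661 fell (462 and 702 adjusted per list), and the 20 others had adjusted p from 0.154 to 0.972. Of the called contigs 44.0% were positive, against 60.2% on log2(FPKM + 1) and 61.7% on log2(FPKM + 0.1), where the median of all contigs lay at 0.204 and 0.315. Per cluster 5202 units were called.

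Anthers and buds of both sexes at stages 6-7 and 8-9 were compared, 12 libraries against 12, to find what marks the anther. Anthers held more AMS (CL1967.Contig8, 3.70, adjusted p = 2.17e-10), AG (CL12699.Contig3, 1.30, adjusted p = 1.17e-12), AP3 (Unigene1187, 1.27), TPD1 (Unigene24793, 1.26), CALS5 (Unigene3860, 1.41), MMD1 (CL1432.Contig1, 1.64), ACOS5 (Unigene33811, 2.07) and CYP703A2 (CL2146.Contig3, 2.39, and 0.80 for its cluster). At stage 8-9 male buds held 521 ± 90 CPM of this last contig and male anthers 487 ± 82, so that its excess in anthers came from other groups. ATHB-40 (CL7969.Contig1, 110 ± 70 against 1.02 ± 2.4 CPM, n = 12, 11.41, and 2.70 for its cluster), MIOX2 (Unigene13637, 16.0 ± 11 against 0.0426 ± 0.079, 8.80) and TULP5 (Unigene32458, 29.8 ± 14 against 0.0866 ± 0.16, 8.61) stood out. Buds held more of a nerolidol synthase (CL1356.Contig36, 0.153 ± 0.23 in anthers against 67.7 ± 68, -9.48), CYP71A9 (Unigene10609, -9.32), a lectin kinase (Unigene7025, -9.30), and a squalene monooxygenase (Unigene3519, -8.67). They also held more of the carpel genes CRC (CL4746.Contig3, -1.68) and INO (CL1363.Contig12, -2.43), which shapes the outer integument, DAD1 (Unigene14959, -2.46) and OPR3 (CL8295.Contig5, -1.84). MS1, MS2, bHLH91, LAP6/PKSA, ABCG26 and A6 had 0 reads in a group, and for their contigs this averaged comparison gave standard errors of 3.73 or more and no call. Summed per cluster, MS1 (3.04, adjusted p = 1.91e-06), MS2 (2.43, adjusted p = 8.35e-08) and bHLH91 (1.53, adjusted p = 1.48e-11) were called higher in anthers.

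Of the contigs 15064 were higher and 12474 lower in anthers, 27538 in all. Higher were tapetum regulators (23 of 50 rose, 1 fell, adjusted p = 5.82e-11; 0.0254 with correlation) and pollen wall (11 of 33 rose, 3 fell, adjusted p = 0.00057; 0.121 with correlation). So were meiosis (17 of 46 rose, 2 fell, adjusted p = 0.0022; 0.214 with correlation) and callose (7 of 20 rose, 2 fell, adjusted p = 0.0222; 0.128 with correlation). Cytokinin (80 of 290 rose, 25 fell, adjusted p = 0.00551; 0.0662 with correlation) and cell death proteases (24 of 88 rose, 9 fell, adjusted p = 0.0469; 0.186 with correlation) were higher too. Lower were cell cycle (14 of 268 rose, 117 fell, adjusted p = 3.85e-14), flavonoid (16 of 138 rose, 68 fell, adjusted p = 7.28e-11) and lignin and secondary wall (22 of 211 rose, 79 fell, adjusted p = 1.47e-06). Lipid and cutin (29 of 332 rose, 136 fell, adjusted p = 1.47e-06), ribosomal proteins (16 of 666 rose, 244 fell, adjusted p = 1.58e-15) and vascular markers (6 of 40 rose, 21 fell, adjusted p = 1.21e-05) were lower too, and these 6 passed with estimated correlation. Photosynthesis was lower (2 rose, 73 fell, adjusted p = 3.05e-15; 0.161 with correlation). So were auxin (75 of 554 rose, 156 fell, adjusted p = 0.0071; 0.264 with correlation) and defence (11 of 120 rose, 49 fell, adjusted p = 2.98e-06; 0.171 with correlation). Pectin (28 of 235 rose, 76 fell, adjusted p = 0.000187; 0.121 with correlation) and late pollen contigs (4 of 45 rose, 12 fell, adjusted p = 0.0306; 0.187 with correlation) were lower as well. The 11 other lists had adjusted p from 0.0922 to 0.984, and over all lists 845 members rose and 1439 fell (851 and 1443 adjusted per list). Of the called contigs 54.7% were higher in anthers, against 42.0% of the 8958 called on log2(FPKM + 1), and the median of all contigs lay at 0.114. Without a fold threshold 52037 contigs passed, and per cluster 11782 units, where the callose, late pollen and protease lists did not pass (adjusted p = 0.348, 0.238 and 0.133, the highest of the 5 settings).

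**Figure D4:**
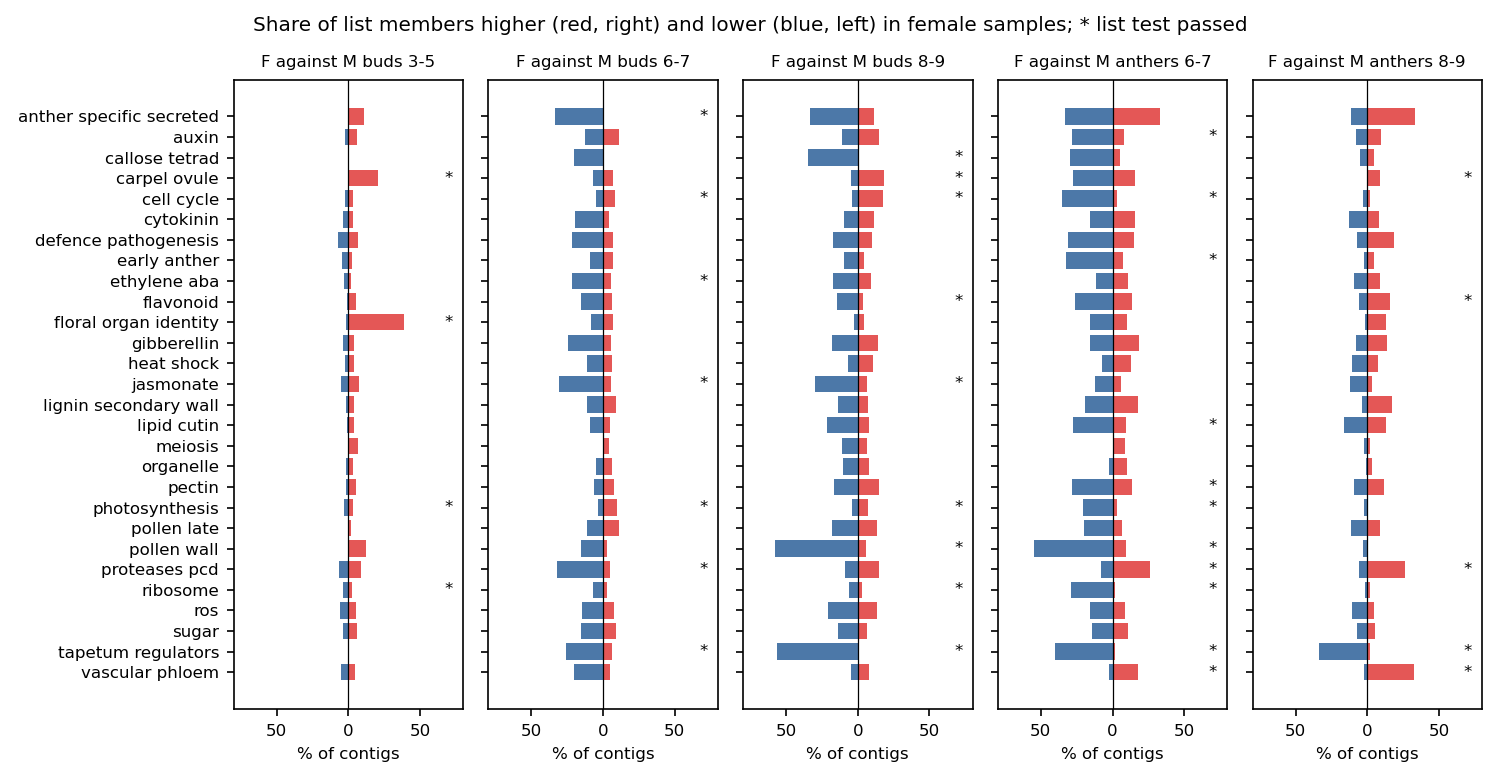
Percent of the contigs of each list called higher or lower in females in the 5 sex comparisons, with a star where the list test passed.

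Over the 5 sex comparisons 36 of the 140 list tests passed; 9 with correlation. The lists of gibberellin, organelle-encoded, reactive oxygen and sugar genes passed in none of the 12 comparisons, with lowest adjusted p-values of 0.131, 0.153, 0.0889 and 0.358. Over the 36 panel genes 63 of 180 sex tests passed, and 63 with the contigs of a cluster summed, of which 5 had not passed as single contigs while 5 others were lost.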

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

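The tests of the sex difference in anthers less that in buds at stage 8-9, of a mix with RNA of the same male anthers, of clusters that part the sexes in anthers 6-7, of gaps among well-counted contigs and of a batch shared by the libraries numbered 2 were chosen after the results were seen.

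Several tapetum and pollen wall genes were high in female anthers 8-9 and low in female buds of the 8-9 class, and for 10 genes picked because they showed this the sex difference in anthers less that in buds was 6.41 for AMS, 8.48 for MS1, 8.41 for CYP703A2, 5.24 for CYP704B1, 6.37 for ACOS5, 9.47 for PKSA, 9.92 for MS2, 9.12 for ABCG26, 9.42 for A6 and 5.41 for QRT3 (log2), which restates the pattern and does not test it. Of the 26 other panel genes 5 had a positive difference (bHLH91 8.35, RBOHE 4.49, CEP1 2.01, the contig matched to TDF1 1.76 and OPR3 1.21), 4 a negative one (DEX1 -2.65, CRC -1.81, GA20OX -1.72 and AG -1.06) and 17, TKPR1 among them (0.87), were not called. A wrong sex label is argued against: of the clusters that part the sexes in anthers 6-7 and were found at 8-9, 89.1% followed the label (65 of 72 male and 58 of 66 female ones), while the planned test was void, with 0 clusters found in 1 sex alone elsewhere. RNA of the same male anthers mixed into the female libraries, at a share near the 0.60 of the male level that 14 pollen wall clusters reached in them, is argued against by 7 of 15516 clusters under 5% of their male level, among them Beta-glucosidase 44 (0.308 against 97.0 CPM), mavicyanin (4.59 against 176) and amino acid permease 3 (0 against 47.4). In these 7 each female library lay at 8.9% or less of the lowest male one, and single female libraries lacked 13 to 23 such clusters against 2 male ones, where single libraries of either sex lacked 1 to 3 against 2 of their own group. The 3-library count was 49 to 227 in the 8 other pairs of groups, and within that range for female clusters in male anthers 8-9. RNA of other male anthers cannot be told apart from female expression, since the 0.03% of abundant male clusters nearly absent in females (1 of 3767) was matched by 0.1% or less in 2 of the 8 other pairs of groups. Female buds of this class may hold anthers at an earlier stage than the dissected ones: genes of female anthers 6-7 reached 7.65 times the share of their anther level in these buds that genes of anthers 8-9 did (1.644% over 7 clusters, interquartile range 0.088 to 4.02, against 0.215% over 58, 0.109 to 0.678). Against anthers of stage 6-7 in these buds stands that clusters expressed at both anther stages reached 13.447% (39 clusters, 5.139 to 30.543), well above the clusters of stage 6-7. A real difference between female anthers and buds stays open too, untested.

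The sex comparisons gave 1483 calls of contigs unread in 1 group but at 5 CPM or more in the other, 1200 in multi-contig clusters. Reads of 1 gene divided differently among near-identical contigs may account for most of these, since 80.9% of the clusters' sums differed by less than 2-fold. A change of the whole gene cannot be told apart from this for the rest: 16.2% had a cluster sum called in the same direction. Allele differences between the sampled plants would give the same picture, and no biological explanation was tested.

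The male and female anther 6-7 libraries numbered 2 stood apart from libraries 1 and 3 of their groups, by 0.133 and 0.103 in correlation. Ribosomal RNA carry-over is argued against: with its 37 contigs left out the smaller gap stayed at 0.103, and among contigs with 5 CPM or more in all 3 libraries, which a loss of reads hardly touches, it was 0.208 (0.025 at most in the other 8 groups). Male buds 8-9, replicate 2, with 29.4% of such reads, correlated with its group at 0.936, as the other 2 did (0.94 and 0.937). Poor RNA quality, which could go with carry-over, was not tested. A library or handling batch shared by both libraries may be involved, as their deviations from the group means correlated at 0.594, but the labels name no batch, so it cannot be told apart from a difference in stage between the samples. No biological explanation was tested.

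The sexes changed differently between stages 6-7 and 8-9 in anthers at 11120 contigs and between stages 3-5 and 8-9 in buds at 14165. In anthers the later minus earlier difference of females less that of males was -1.20 for TPD1, 3.43 for AMS, 4.96 for CYP703A2, 3.93 for ACOS5, -1.53 for CALS5, 1.18 for PI, 3.49 for CRC, 3.00 for INO and 3.21 for RBOHE. For MS1, bHLH91, PKSA and ABCG26, unread in a group, only the adjusted p is given: 0.0127, 2.68e-09, 0.0216 and 0.000813. In buds it was -12.42 for MS1, -11.03 for bHLH91, -9.80 for CYP703A2, -6.37 for CYP704B1, -8.29 for ACOS5, -11.95 for PKSA, -13.58 for MS2, -13.80 for ABCG26, -1.15 for CALS5, -13.49 for A6, -6.29 for QRT3, -2.00 for AG, -2.27 for AP3, -2.41 for CRC, -2.01 for OPR3, -4.95 for DAD1, 2.07 for GA20OX, 1.91 for CEP1 and -4.90 for RBOHE. AMS, unread in a group of buds, had an adjusted p of 0.000707.

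Only the real split of libraries (1 of 31) reached its count in the interactions of anthers (4166 contigs, highest other 2) and buds (20077, highest other 3.51% of that) and in anthers against buds (26981, highest other 10). These splits break up all group differences, so they do not test an interaction alone. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05: on the 6 libraries alone the real counts were 10332, 16721 and 18445 in the buds of stages 3-5, 6-7 and 8-9, 2740 and 15829 in the anthers of stages 6-7 and 8-9, 6786 and 8535 between stages of male and female anthers and 29777 and 24204 between stages of male and female buds, and the highest other was 0 in each.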

How the results depend on the processing

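The fits per cluster, without ribosomal RNA contigs, without both anther 6-7 libraries numbered 2 or the 3 doubted libraries, the block on 6 libraries and the list tests in other settings were chosen after the results were seen. Of 154 counts in other settings 125 lay within 1.5 times the reported one, and 7 settings moved none by more, the replicate block over all 30 libraries among them. Per cluster, 2403, 6400 and 6785 units differed between the sexes in buds (stages 3-5, 6-7 and 8-9) and 9748 and 5439 in anthers (6-7 and 8-9). Between stages it was 7816 in male and 7370 in female anthers and 12888 in male and 9125 in female buds, in the interactions 4889 (anthers) and 5202 (buds), and between tissues 11782; fewer units by construction, 41850 in place of 97727. On log2(FPKM + 1), which draws low contigs together, counts were 4152, 8132, 10027, 11147 and 6642 between the sexes in the same order, 9340, 8594, 16401 and 11690 between stages and 8958 between tissues. From 6 libraries alone 2740 contigs were called between the sexes in anthers 6-7, 6786 between the stages of male anthers and 8535 between those of female anthers. A replicate block in the first, where both libraries numbered 2 deviated together, gave 12901. Without a fold threshold 52037 contigs differed between tissues. The interaction in anthers gave 18015 contigs without both libraries numbered 2, 18252 without the 3 doubted libraries, and 8632 (without male anthers 8-9 replicate 3) to 18022 (without female anthers 6-7 replicate 2) with 1 library left out, the sole count of 102 that moved by over 1.5 times; the cause was not tested. With an estimated correlation 9 of the 36 list calls between the sexes were kept. Per cluster 20 of the 108 list calls over all comparisons were lost and 16 gained, on log2(FPKM + 1) 9 and 11, on log2(FPKM + 0.1) 3 and 10, without the 3 doubted libraries 8 and 21 and with DESeq2 size factors 0 and 0. Of 3362 gene values 2 turned, both per cluster: CYP703A2 (CL2146.Contig3) in buds 6-7, from -4.10 to 0.06, and CYSEP (CL126.Contig8) in anthers 6-7, from -14.20 to 1.89. Of 1542 values with 1 library left out 1 turned: that of MS2 CL7301.Contig5, female against male anthers, anther stage 6-7, was 0.00 without male replicate 1, where the male reads lay, and -10.48 without male replicate 2. Of these 1542, 53 (of 14 gene values) were no longer called, and in other settings 47 were no longer called and 22 newly so. Of 241 called gene values 86 moved by over 1.5-fold without 1 library, 65 of them with a mean under 1 CPM in the lower group; MS2 and A6 moved most, without replicate 1 of male anthers 6-7. RBOHE in buds 6-7 and BEL1 in anthers 8-9 were not called on log2(FPKM + 1). Depth limits contigs near 0.071 to 0.0907 CPM, 3 counts per library.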

Other observations

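The share of polymerase contigs was measured after the results were seen. The meiotic cyclin SDS (CL3308.Contig1) fell from stage 6-7 to 8-9 in anthers of both sexes: 6.56 ± 2.5 to 0.396 ± 0.22 CPM in males (log2 -4.04, adjusted p = 7.31e-05) and 4.42 ± 2.7 to 0.315 ± 0.065 in females (-3.80, adjusted p = 0.00015). MMD1 (CL1432.Contig1), a meiotic PHD-finger factor, rose from stage 3-5 to 8-9 in buds of both sexes, from 1.07 ± 0.056 to 7.65 ± 2.9 CPM in males (2.84) and from 1.11 ± 0.16 to 6.50 ± 2.1 in females (2.55), and did not pass in any of the 5 sex comparisons. The recombinase DMC1 (CL9535.Contig2) ran from 57.6 ± 3.5 to 109 ± 4.0 CPM over the 10 groups, with no call between the sexes. SPO11-1 (CL4528.Contig2), which makes the meiotic breaks, was called once between the sexes, at 4.53 ± 3.0 against 1.49 ± 0.62 CPM in female and male anthers 6-7 (1.60, adjusted p = 0.00728). It was not called there from the 6 libraries alone (1.68, adjusted p = 0.323), with a replicate block on them (1.44, 0.0707), on log2(FPKM + 1) (0.73, 0.0476) or on log2(FPKM + 0.1) (1.09, 0.128).

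The ovule identity gene STK/AGL11 (CL7391.Contig2) rose with bud stage in both sexes: from 0.137 ± 0.041 to 7.05 ± 0.61 CPM in females (5.66, adjusted p = 6.5e-06) and in males from 0 reads to 3.06 ± 0.69 CPM. Between the sexes it was called in the smallest buds (adjusted p = 0.0286), where the female level lay near the floor, and did not pass in the other 4 comparisons. The call was lost without any of the 3 male libraries (adjusted p = 0.0836 to 0.0869), without female replicate 1 (0.0528) or 2 (0.08), on log2(FPKM + 1) (0.21, adjusted p = 0.968) and on log2(FPKM + 0.1) (1.33, 0.346).

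A total of 5 contigs with an RNA-dependent RNA polymerase domain and no SwissProt name took up to 1.211% of the counts of a library. They took 0.972 to 1.007% in female buds 3-5 against 0 to 0.003% in male ones, 0.293 to 0.44% in female buds 6-7 against 0.355 to 0.508%, and 0 to 0.001% in female buds 8-9 against 0.001 to 0.018%. In anthers 6-7 they took 0.171, 1.05 and 0.177% in female libraries 1 to 3, of which number 2 stood apart from its group, against 0% in male ones. In anthers 8-9 they took 0.372 to 0.392% in female and 0.776 to 1.211% in male libraries.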
